A study of Canis lupus familiaris with 4 samples.

How the data were processed

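The series holds 4 messenger RNA libraries of canine CD8+ T cells. Per the labels and the series' design text, blood mononuclear cells of 2 healthy dogs were grown for 14 to 20 days with IL-2 (2500 IU/mL) plus 2-mercaptoethanol (50 µM), the CD8+ cells were purified, and each dog gave 1 culture with exosomes of the canine B cell lymphoma line CLBL-1 and 1 with PBS. The treatment label lists 50, 100 and 200 µg/mL, while the series' own design text gives 50 µg/mL for the sequenced cells.

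Per the submitters' processing notes, FastQC, MultiQC, Trimmomatic 0.38, HISAT2 2.1.0, featureCounts 1.6.0 and the build CanFam3.1 were used. Their order and settings, and whether counting used strand, are not given in the sources used here. Per the file headers and the log, the authors compared 1 exosome library with 1 control library per table by DEGseq, after reducing 30951 genes to 11838 and removing 89 and 58 genes as outliers from the tables of pair 1 and pair 2. The gene columns deposited by the authors are a signal, namely read counts divided by 1 factor per library. The authors' mean column is a score, the average of both columns of a table. The authors' log2 fold changes are exosome over control. The authors' p-values, raw and adjusted, each come from 1 library against 1 and so compare libraries, not conditions.

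Each table held 1 control and 1 exosome column. The tables are named by dog, but their columns carry 24 h in one and 48 h in the other, whereas the labels give 48 h for every library. Columns were therefore assigned to control or exosome only. The table with 24 h in its column names is called pair 1 and the table with 48 h pair 2. By the design text and the names of the tables, the pairs are different dogs. Any difference in sex goes with the dog, and whether exposure time differs too stays open. The pair was used as the block because the authors tested the columns of a table against each other. The deviations of control and exosome libraries of a pair from their group means correlated at 0.818 across genes, a value that is equal for both pairs by construction with 2 pairs.

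All values (100%) were whole multiples of the smallest value in their column, within a tolerance of 0.001, so reads per gene could be recovered. The authors' factors lay within 0.89% of DESeq2-type factors computed over all 4 libraries together and within 1.1% of TMM factors, so values were compared across both tables. No gene was listed at 0. Recovered reads over the 11691 genes in both tables were 12325953 and 10056143 for the control and exosome library of pair 1 and 9417298 and 12046358 for those of pair 2. These sums leave out the genes that the authors removed, and the total depth is unknown.

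Before the data were examined, edgeR on counts was planned, with limma on log2(value + 1) as the test if the files held normalized values. They did, so limma 3.58.1 in R 4.3.3 gave the main result, with the pair as a block, 1 residual degree of freedom, a prior of 11.4 degrees of freedom and Benjamini-Hochberg adjustment at 0.05 over 11691 genes. A fold on this scale understates the change of low genes. edgeR 4.0.16 (quasi-likelihood), limma-voom and DESeq2 1.42.0 were run on the recovered reads with the same block. Within a pair there is 1 library per arm, so folds are TMM-scaled log2 CPM differences with a prior count of 2 and have no test. Of 35 gene lists fixed beforehand, 33 had at least 5 measured genes and were tested by camera with a preset correlation of 0.01, on log2(value + 1) in place of the voom values first planned. An estimated correlation and fry stand beside it. The median of a list in a pair was ranked among 10000 random lists matched on mean expression in 50 bins. Their members were drawn independently, so the ranks do not allow for genes that vary together.

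Genes were named by a rule fixed beforehand: the 12 highest and 12 lowest log2 folds among called genes with a symbol, the same direction in both pairs and at least 50 reads in the higher library of each pair; up to 4 members per list with at least 50 reads in the higher library of at least 1 pair, called ones first; the 6 highest and 6 lowest folds in each pair among genes with a symbol and at least 200 reads in the higher library; and label checks (CD8A, CD8B, CD4, CD3E, MS4A1, and XIST, which was not among the shared genes). Other names are marked as chosen later or as outside the rule. Some genes that the rule selects are not reported here. Of the shared genes, 10464 carry a symbol and 341 carry 2 or more, which are treated as uncertain because reads of several genes share 1 identifier. Of 10469 gene numbers in the table of pair 1, 9861 were found in a reference table of the assembly UU_Cfam_GSD_1.0, used for names only. The files give no positions, and no genome was used.

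The scripts were tested on counts simulated for these 4 libraries and 11691 genes with 200 changed genes. In 1 drawing limma recovered 5.97% of genes changed 1.5-fold, 44.8% of those changed 2-fold and 98.5% of those changed 4-fold; edgeR recovered 8.96%, 47.8% and 98.5%. Over 10 such drawings limma recovered 32.4% of genes changed 2-fold, against 43.6% for edgeR, 44.6% for voom, 28.4% for DESeq2 and 43.3% for limma with a variance trend. In these drawings 11.6% of limma's calls were false (range 1.35% to 18.3%). The rates were 4.39% for edgeR, 5.39% for voom, 0.781% for DESeq2 and 4.91% for limma with a variance trend. Of limma's 127 false calls over the 10 drawings, 120 had a mean value under 20, and 0.99% of its calls at 20 or more were false. In the single drawing above, 34 of limma's 143 calls were false, against 7 of 121 for edgeR and 0 of 89 for DESeq2. Each gene was drawn with the dispersion of the trend at its expression level, without gene-specific spread. edgeR made 1163 calls over the 10 drawings but 0 on the real data, so these rates may not carry over. camera called the 1 simulated lowered list and 0 of 32 unchanged lists. The simulated genes varied independently, so this could not show false calls of lists whose members vary together.

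Some alternatives were added after the data were seen, several of them after a first look at their outcome. They were limma without the block, other pseudocounts, a mean value of at least 5 and a variance trend. Values scaled to the recovered totals in limma and other pseudocounts in camera were added too. edgeR with the block and camera on voom values were the tests first planned for counts. They were set beside the main test once scaled values were found. Alternatives covered the tool, the block, the scaling, the filter, the pseudocount, the prior count, the threshold and each library left out. Groups of 2 libraries allow neither a test of other splits of the samples nor a search for outlying libraries.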

Results

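Messenger RNA was sequenced from cultured CD8+ T cells of healthy dogs after culture with exosomes of CLBL-1, a canine diffuse large B cell lymphoma line, or with PBS. The labels give 48 h of exposure for every library, while the deposited columns of pair 1 are named 24 h and those of pair 2 48 h. Exosomes are small vesicles that cells release. The control group and the exosome group held 2 libraries each, which form 2 pairs. The recovered depth was 9417298 to 12325953 reads per library over 11691 genes. Expression is given as scaled read counts as deposited by the authors, and each value is a single library. The log2 values of the libraries correlated at 0.969 within pair 1 and 0.982 within pair 2 across genes, and at 0.891 to 0.912 between pairs; genes are not independent replicates.

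The cells carried T cell transcripts in every library. CD8A, a chain of the CD8 coreceptor, stood at 385 and 286 in the control and exosome libraries of pair 1 and at 488 and 453 in those of pair 2. CD3E, a part of the T cell receptor complex, stood at 675 and 530 in pair 1 and 873 and 750 in pair 2. CD8B differed between the pairs, at 73.4 and 72.7 in pair 1 and 479 and 528 in pair 2. CD4 was at 3.22 to 11.6, and MS4A1, a B cell marker, at 3.62 to 10.7. None of these genes passed the test for the treatment (limma, smallest adjusted p = 0.31, for MS4A1).

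The main comparison asked which transcripts differed between T cells with lymphoma exosomes and their PBS controls. The 3 gene lists with the smallest camera adjusted p-values were lower with exosomes: cell cycle (3.8e-23), mitochondrially encoded (3.7e-08) and cholesterol synthesis transcripts (1.5e-07). None was called with an estimated correlation (adjusted p = 0.92 for each) or by fry (adjusted p = 0.41, 0.53 and 0.41), and the cholesterol call was lost in 2 of 4 fits that leave out 1 library. Both the estimated correlation and fry rest on 1 residual degree of freedom and could hardly call any list here. The smallest unadjusted camera p with an estimated correlation was 0.12, for cholesterol synthesis. Their outcome therefore decides little, and the camera calls rest on the preset correlation. Among single genes, the circadian repressor PER1 rose from 8.32 to 47.8 in pair 1 and from 6.69 to 29.4 in pair 2. Its log2 fold was 2.19 ± 0.24 (SE, limma adjusted p = 0.00326). The SE given for single genes is limma's moderated one, with 1 residual and 11.4 prior degrees of freedom. It draws mostly on the variances of all genes and does not measure the spread of the 2 pairs. The cytokine LIF fell from 42.8 to 7.79 in pair 1 and from 53.6 to 15.4 in pair 2, a log2 fold of -2.02 ± 0.24 (adjusted p = 0.00585 by limma). In total 29 genes were higher and 58 lower with exosomes by limma. All 87 had the same direction in both pairs. With 2 pairs the paired call in effect requires this, so it is no separate evidence that the pairs agree.

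These calls depend strongly on the test. edgeR with the same block called 0 genes (655 higher and 985 lower at an unadjusted p under 0.05), voom called 0 (709 and 1029), and DESeq2 called 62 higher and 107 lower, of which 67 were among the 87. Without the pair block, limma called 0 (209 genes at an unadjusted p under 0.05, against 696 higher and 1164 lower with the block). limma also called 0 genes with a pseudocount of 0.1 or with values scaled to the recovered totals, and 202 higher and 408 lower genes with a pseudocount of 5. With DESeq2 size factors edgeR called 7 higher and 7 lower, and with upper-quartile factors 4 and 3. Of the 87 called genes, 40 had a mean value under 20. That range held 120 of limma's 127 false calls on simulated data, where 11.6% of its calls were false. The simulation left out gene-specific spread of the variance, so this rate may not hold for the 87 genes.

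Among the 12 genes named as highest with exosomes, all with a symbol and at least 50 reads in the higher library of each pair, B4GALNT4, a glycosyltransferase, rose from 4.32 to 32.2 in pair 1 and from 7.43 to 31.1 in pair 2. ABCG1, a cholesterol exporter, rose from 1.49 to 16.1 and from 4.03 to 14.4. TSC22D3, a glucocorticoid-induced regulator also called GILZ, rose from 107 to 403 and from 52.3 to 140. BCL6, a transcriptional repressor, rose from 18.0 to 56.6 and from 13.6 to 35.5. VEGFA, an angiogenic growth factor, rose from 55.6 to 394 in pair 1 and from 8.81 to 16.4 in pair 2, but was not called by DESeq2 (adjusted p = 0.342). RGS2, a regulator of G protein signalling, rose from 44.3 to 242 and from 2.23 to 4.80. INPP5F, a phosphoinositide phosphatase, rose from 66.0 to 316 and from 37.7 to 72.1. The others of the 12 were DDIT3, PCDH18, CCDC155 and SMIM3, with log2 folds of 1.38 to 1.62. Adjusted p-values of the 12 by limma ran from 0.00326 to 0.0453.

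**Figure D1:**
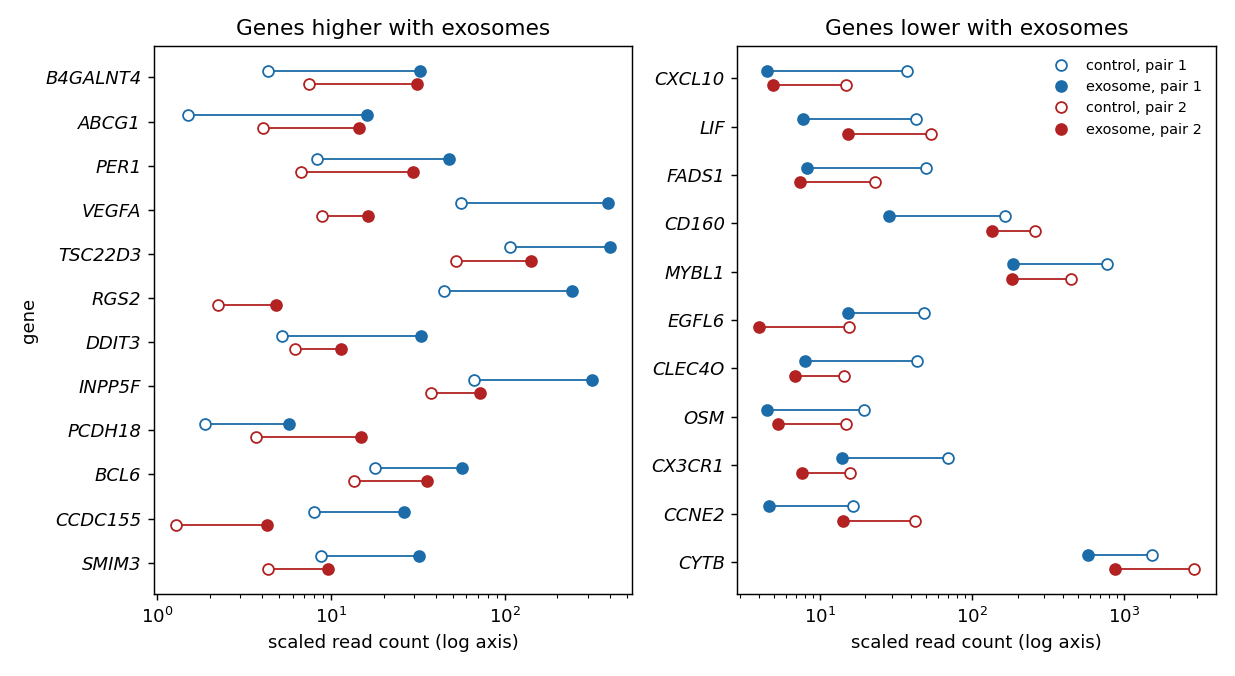
Scaled read counts (log axis) of genes named as higher and as lower with exosomes, where open points are control libraries, filled points exosome libraries, and a line joins the 2 libraries of a pair. PER1 rose from 8.32 to 47.8 in pair 1 and LIF fell from 42.8 to 7.79.

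Among the 12 genes chosen as lowest by the same limits, CXCL10, an interferon-induced chemokine, fell from 37.4 to 4.54 in pair 1 and from 15.0 to 4.96 in pair 2. FADS1, a fatty acid desaturase, fell from 49.8 to 8.28 and from 23.0 to 7.39. CD160, a receptor of cytotoxic lymphocytes, fell from 165 to 28.5 and from 259 to 136. MYBL1, a transcription factor, fell from 775 to 186 and from 448 to 183. CX3CR1, the fractalkine receptor found on effector T cells, fell from 70.0 to 14.1 and from 15.9 to 7.63. EGFL6 fell from 48.7 to 15.4 and from 15.6 to 4.01, and CLEC4O from 44.0 to 8.09 and from 14.5 to 6.92. Among the 12 were also LIF, OSM, CCNE2 and CYTB, described elsewhere. Adjusted p-values of the 12 by limma ran from 0.00585 to 0.0348.

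Cell cycle genes were lower as a group. Of 36 measured members of the proliferation list, 34 had lower values with exosomes in both pairs, 3 were called over all genes and 34 when adjusted over the list alone. The median log2 fold was -0.82 in pair 1 and -0.91 in pair 2, and none of the 10000 matched random lists reached either value. Members of the random lists were drawn independently, so this rank does not allow for cell cycle genes that vary together. CCNE2, cyclin E2, fell from 16.7 to 4.63 in pair 1 and from 42.5 to 14.2 in pair 2. RRM2, a ribonucleotide reductase subunit, fell from 125 to 39.1 and from 311 to 145, and MCM5, part of the replicative helicase, from 50.7 to 19.8 and from 132 to 55.8. PCNA, the replication clamp, stood at 127 and 62.4 in pair 1 and 273 and 122 in pair 2 (adjusted p = 0.0526 by limma). The list was called by camera (adjusted p = 3.8e-23), but not with an estimated correlation (adjusted p = 0.92 with an estimated correlation). The CD8 T cell markers had medians of -0.34 in pair 1 and 0.01 in pair 2.

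Transcripts of the mitochondrial genome were also lower as a list, but not evenly. All 9 measured members had lower values in both pairs, 3 were called over all genes and 8 when adjusted over the list alone, with medians of -0.85 in pair 1 and -1.32 in pair 2. CYTB, a subunit of complex III, fell from 1531 to 581 in pair 1 and from 2878 to 879 in pair 2. ND1 and ND3, subunits of complex I, fell from 1923 to 927 and from 196 to 93.2 in pair 1, and from 3584 to 1129 and from 364 to 123 in pair 2. ND4L stood at 795 and 632 in pair 1 and at 2045 and 605 in pair 2 (adjusted p = 0.109 by limma). The members with the smallest folds, chosen after their values were seen, were COX1, at 24348 and 22860 in pair 1 and 29465 and 26070 in pair 2, COX2, at 4780 and 4141 and then 9112 and 4787, and ATP8, at 323 and 280 and then 787 and 308. The 9 transcripts took 4.06% of the reads in the control and 3.27% in the exosome library of pair 1, and 5.72% and 4% in pair 2. Nuclear genes of oxidative phosphorylation were not called as a list (29 members, camera adjusted p = 0.79). The mitochondrial list had a camera adjusted p of 3.7e-08 (adjusted p = 0.92 with an estimated correlation).

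Of 24 measured genes of cholesterol synthesis and uptake, 20 had lower values in both pairs, 3 were called and 11 were lower when adjusted over the list alone, while 1 was higher. SQLE, squalene epoxidase, fell from 93.5 to 37.9 in pair 1 and from 224 to 106 in pair 2, and DHCR7, which makes cholesterol in the last step of a branch of the pathway, from 25.3 to 8.48 and from 51.9 to 27.4. The medians were -0.45 in pair 1 and -0.49 in pair 2 (camera adjusted p = 1.5e-07; adjusted p = 0.92 with an estimated correlation). Without the block, the call was lost when the exosome library of pair 1 (adjusted p = 0.279) or the control library of pair 2 (0.325) was left out. The lipid uptake list, which holds both ABCG1 and FADS1, was not called (camera adjusted p = 0.86).

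Cytokine genes were lower on balance, mainly in pair 1. Of 19 measured members 10 had lower values in both pairs, 3 were called and 10 were lower when adjusted over the list alone, while 1 was higher. OSM, a cytokine of the LIF family, fell from 19.6 to 4.54 in pair 1 and from 14.9 to 5.35 in pair 2, and LTA, lymphotoxin alpha, from 55.3 to 19.2 and from 36.4 to 18.2. CCL1, a chemokine, stood at 120 and 56.6 in pair 1 and 1.70 and 0.708 in pair 2. The medians were -1.09 and -0.21 (camera adjusted p = 0.00038; adjusted p = 0.92 with an estimated correlation). The type I interferon list (31 genes, 0 called, 4 lower when adjusted over the list alone) was called lower with medians of -0.57 in pair 1 and -0.05 in pair 2 (camera adjusted p = 0.00099; adjusted p = 0.92 with an estimated correlation). The cytokine call was lost without the control (adjusted p = 0.0726) or the exosome library (0.206) of pair 1, and the interferon call without the exosome library of pair 1 (0.691, direction turned) or the control library of pair 2 (0.366).

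The heat shock list was lower (15 genes, 0 called, 2 when adjusted over the list alone; medians -0.22 and -0.33). HSPA8, the constitutive chaperone HSC70, stood at 1263 and 603 in pair 1 and at 2585 and 1495 in pair 2 (adjusted p = 0.07 by limma). The list's camera adjusted p was 0.035 (adjusted p = 0.92 with an estimated correlation), and it was lost without the exosome library of pair 1 (0.931) or the control library of pair 2 (0.717, direction turned).

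Genes of the amino acid response were higher. Of 22 measured members 12 had higher values in both pairs, 2 were called and 6 were higher when adjusted over the list alone. ATF4, the transcription factor that directs this response, rose from 395 to 1105 in pair 1 and from 394 to 792 in pair 2, and SLC7A5, a transporter of large neutral amino acids, from 32.9 to 120 and from 28.9 to 53.3. TRIB3, a target of ATF4, stood at 1.26 and 8.19 in pair 1 and 2.02 and 3.93 in pair 2 (adjusted p = 0.0526 by limma). The medians were 0.39 and 0.26 (camera adjusted p = 0.00038; adjusted p = 0.92 with an estimated correlation), and the call was lost without the control library of pair 1 (0.0726). The list of endoplasmic reticulum stress genes was called higher (21 genes, camera adjusted p = 0.047; adjusted p = 0.97 with an estimated correlation), but its medians were 0.47 in pair 1 and -0.06 in pair 2. Its 1 called member, DDIT3, a stress-induced transcription factor, rose from 5.18 to 32.8 and from 6.16 to 11.4. This call was lost without the block (0.0665), with values scaled to the recovered totals (0.0563), with a pseudocount of 0.1 (0.0758), and without the control library (0.144) or the exosome library (0.25, direction turned) of pair 1 or the control library of pair 2 (0.282).

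The memory and naive T cell list was higher, with 10 of 14 members at higher values in both pairs, 1 called (BCL6) and 3 when adjusted over the list alone. The medians were 0.88 and 0.30 (camera adjusted p = 0.00013; adjusted p = 0.92 with an estimated correlation). Ribosomal protein genes were higher by a small amount, with 39 of 54 at higher values in both pairs, 0 called singly, 0 when adjusted over the list alone, and medians of 0.09 and 0.30 (camera adjusted p = 0.00038; adjusted p = 0.92 with an estimated correlation). Both calls were lost without the control library of pair 1 (0.766 for the memory list and 0.9 for the ribosomal list) or the exosome library of pair 2 (0.956 and 0.718), with the direction turned in 3 of these 4 fits.

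**Figure D2:**
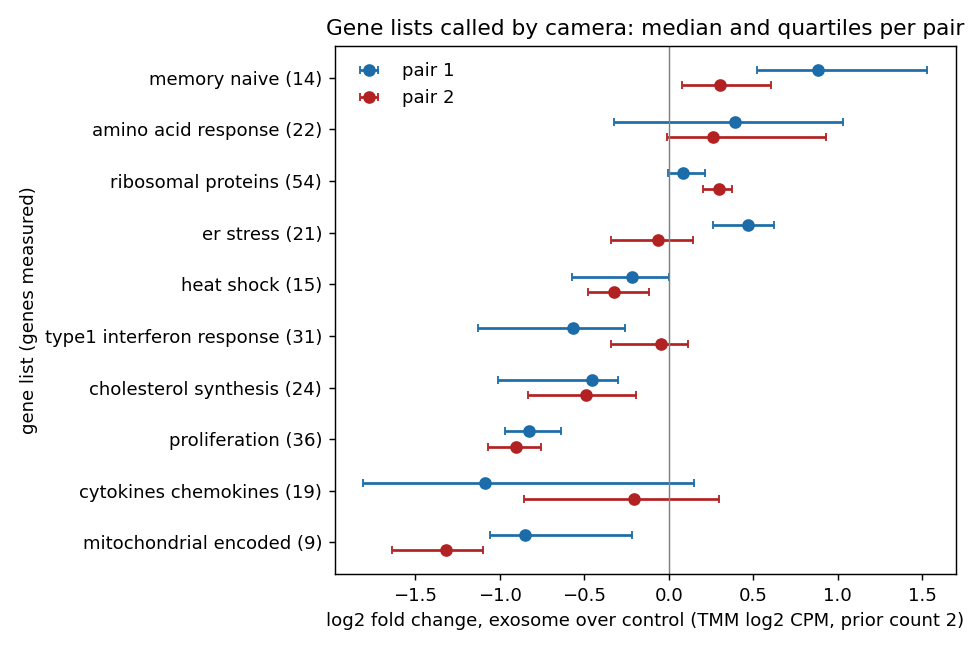
Median (point) and quartiles (bar) of the log2 fold change, exosome over control, of the 10 gene lists called by camera, by pair, with the number of measured genes in brackets. The proliferation list lies at -0.82 in pair 1 and -0.91 in pair 2, and the endoplasmic reticulum stress list has medians of opposite sign.

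The remaining 23 tested lists were not called. Cytotoxic effector genes (18 measured, 0 called, 1 higher and 2 lower when adjusted over the list alone) had medians of -0.25 in pair 1 and -0.02 in pair 2 (camera adjusted p = 0.86). CTSC, the protease that activates granzymes, stood at 601 and 351 in pair 1 and 490 and 208 in pair 2 (adjusted p = 0.0627 by limma). Among 18 inhibitory receptor genes (camera adjusted p = 0.4) only CD160 was called, while CTLA4 stood at 0.942 and 7.69 in pair 1 and 7.54 and 13.4 in pair 2 (adjusted p = 0.0505). In the activation list (20 genes, camera adjusted p = 0.86), the IL-2 receptor chain IL2RA stood at 93.9 and 34.1 in pair 1 and 51.5 and 31.1 in pair 2 (adjusted p = 0.0621). The NF-kappaB list had medians of 0.25 and 0.13 (adjusted p = 0.13), with its member TNFAIP3 at 84.5 and 333 in pair 1 and 52.3 and 77.4 in pair 2 (adjusted p = 0.0651).

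Camera adjusted p-values of the other lists were 0.33 for interferon gamma and antigen presentation, 0.56 for effector transcription factors, 0.62 for the TGF-beta response, 0.72 for T cell receptor signalling, 0.78 for glycolysis and hypoxia, 0.86 for apoptosis and p53 and for oxidative stress, 0.93 for immediate early genes, 0.97 for vesicle and tetraspanin genes and 1 for chemokine receptors. Median and test differed in sign for the T cell receptor, activation and monocyte lists, and mean and test for the immediate early, monocyte and vesicle lists. Among markers of other cell types, adjusted p-values were 0.052 for CD4 T cells (medians 0.44 and 0.34), 0.19 for plasma cells, 0.24 for B cells (medians -0.83 and -0.17), 0.31 for NK cells, 0.86 for dendritic cells and 0.93 for monocytes and macrophages, beside 0.86 for CD8 T cells. The neutrophil list had 4 measured genes and the erythroid and platelet list 2, too few for a test. Of these, MMP9 fell from 439 to 146 in pair 1 and from 171 to 81.6 in pair 2 (adjusted p = 0.0326 by limma), and ITGB3 stood at 4.002 and 27.12 in pair 1 and 0.106 and 0.472 in pair 2 (adjusted p = 0.0767).

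Within each pair, where 1 library stands for an arm and no test applies, more genes differed by 2-fold in pair 1 (415 higher, 818 lower) than in pair 2 (318 higher, 273 lower). Among genes with a symbol and at least 200 reads in the higher library, the highest folds in pair 1 belonged to SIK1, a salt-inducible kinase, with 0.471 in the control and 23.3 in the exosome library, and to OCIAD2 (3.30 and 109), HOMER3 (0.942 and 27.4), PRDX6 (11.7 and 204), ESYT3 (16.9 and 291) and NETO2 (5.26 and 76.4). The lowest included MYC, the growth-promoting transcription factor (127 and 23.3), ZNF683, the tissue-residency factor HOBIT (543 and 96.9), and LOC607096 (29.4 and 3.06). In pair 2 the values of MYC were 176 and 122 and those of ZNF683 208 and 148. Among such genes with a symbol, the highest folds in pair 2 belonged to EXD1 (10.6 and 49.4), PER1, B4GALNT4, HFE (6.79 and 22.2), UNKL (9.98 and 29.3) and ZFP36L2 (20.7 and 58.5). The lowest of them were those of LIF, ND4L, CYTB, DPY19L1 (25.5 and 7.71), ND1 and FADS1.

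The fold changes of the 2 pairs, which share no library, correlated at a Pearson r of 0.312 and a Spearman rho of 0.315 across 11691 genes, which are not independent replicates, and 60.6% of genes had the same sign. With at least 50 reads in the higher library of each pair (9512 genes), r was 0.41. A 2-fold change in the same direction in both pairs was found for 58 genes higher (11.3 for independent lists) and 104 lower (19.1), and in opposite directions for 38 (31.9). With the 50-read limit, 25 were higher (3.05), 57 lower (5.72) and 7 opposite (8.94).

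**Figure D3:**
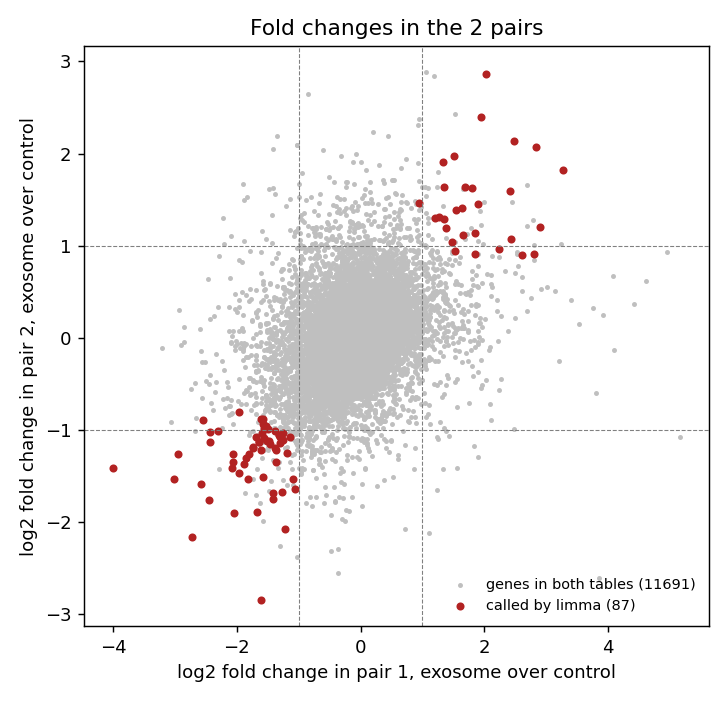
Log2 fold change, exosome over control, in pair 1 (x axis) and pair 2 (y axis) for 11691 genes in grey, with the 87 genes called by limma in red and dashed lines at 2-fold. The folds correlate at r = 0.312. The called genes lie at the lower left and upper right, which the paired call in effect requires.

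The authors' deposited tables, at an unadjusted p of 0.05 and a 1.5-fold change in tests of 1 library against 1, list 1380 genes for pair 1 (617 higher, 763 lower) and 582 for pair 2 (234 higher, 348 lower). By the authors' adjusted p under 0.05, 930 and 281 of them would remain. Among genes in both of the authors' deposited tables, 61 were higher in both lists (12.3 for independent lists; Fisher's exact test across genes, two-sided, p = 1.3e-26) and 167 lower in both (22.6; p = 6.6e-108), while 6 had opposite directions (33.5). Genes are not independent replicates, so these Fisher p-values do not measure how the response repeats over dogs. Of the 87 genes called by limma, 55 were among those shared calls, including LIF, whose product is a cytokine of the IL-6 family. The authors' deposited log also lists 2336 genes between the control libraries of the pairs and 2664 between the exosome libraries.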

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

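The tests of library depth and of genes with few reads were written before their results were seen; the selection of single genes below followed the naming rule, and no test here was chosen after its result was seen.

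The responses of the 2 pairs pointed in opposite directions for some lists, which flagged them; with 1 library per arm in each pair these differences were not tested. Median log2 folds in pair 1 and pair 2 were 0.467 and -0.0612 for endoplasmic reticulum stress, -0.027 and 0.101 for T cell receptor signalling, -0.238 and 0.048 for glycolysis and hypoxia, and 0.036 and -0.154 for nuclear oxidative phosphorylation genes. They were 0.2 and -0.0765 for activation, -0.341 and 0.0101 for CD8 T cell markers, -0.326 and 0.309 for dendritic cell markers, and 0.000244 and -0.0321 for oxidative stress. They were -0.167 and 0.161 for immediate early genes, -0.191 and 0.202 for monocyte markers, -0.037 and 0.0674 for vesicle genes, and 0.0808 and -0.0615 for chemokine receptors. Several of these medians lie near 0, where a difference in sign says little.

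Single genes also moved in opposite directions, untested. The log2 folds in pair 1 and pair 2 were 5.16 and -1.07 for SIK1, 4.09 and -0.128 for PRDX6, 3.8 and -0.594 for NETO2, -0.027 and 0.171 for CD8B and 0.943 and -0.0406 for CD4.

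Genes kept by the authors in 1 table only take no part in the comparisons, and by the authors' rule 3 of them were higher with exosomes and 3 lower (ND2, ND4 and ENOX1), all in pair 1. Of those higher, PDK4, a kinase that inhibits pyruvate dehydrogenase, stood at 14.4 with exosomes and 1.49 in the control, IL13RA1, an IL-13 receptor chain, at 9.27 and 1.65, and the unnamed ENSCAFG00000009414 at 9.57 and 0.471. Each value is 1 library, and pair 2 has no value for these genes.

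More genes differed 2-fold in pair 1 than in pair 2 (1233 and 591). Depth of the libraries is argued against, since after thinning all libraries to 9417298 reads the ratio was 2.04 (median of 10 drawings, lowest 1.98). Genes with few reads do not account for it either, since the ratio was 3.58 among genes with at least 200 reads (397 and 111 of 7215). Dog, sex or exposure time may each underlie the difference, but they cannot be told apart, because there is 1 pair for each dog and column time. Differences in the culture of each dog's cells were not tested.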

How the results depend on the processing

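limma without the block, other pseudocounts, a mean value of at least 5 and a variance trend were added after the data were seen. So were limma on recovered totals and log2(value + 1) folds. edgeR with the block and camera on voom values were the tests first planned for counts. They became alternatives once scaled values were found. The other fits were planned as alternatives.

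Counts of genes moved the most. Against 29 higher and 58 lower genes by limma, DESeq2 called 62 and 107, edgeR with DESeq2 size factors 7 and 7 (50% higher) and with upper-quartile factors 4 and 3 (57.1% higher). limma called 202 and 408 with a pseudocount of 5, 178 and 380 at a mean value of at least 5, 205 and 402 with a variance trend, and 150 and 328 at an adjusted p under 0.10. The count was 0 in both directions for edgeR with the block (1640 genes at an unadjusted p under 0.05), with library totals (1712), with at least 50 reads in 2 libraries (1546), for voom (1738), and for limma with a pseudocount of 0.1 (1571) or recovered totals (1471). edgeR without a filter also gave 0, but its filter removes no gene here, so that setting tests nothing. A 2-fold limit kept 29 and 58. Under these settings each of the 87 genes that was tested kept its direction, and the cause was not tested.

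Without the pair as a block (no replicate block), edgeR called 0 genes (194 at an unadjusted p under 0.05), limma called 0 (209), and camera called 9 lists. The block was kept because the authors compared the columns of a table. By the design text it stands for the dog, and whether it also stands for exposure time is open. In leave-one-out fits by limma, where the lone library of an arm is assumed to vary like the other group, the counts were 0 to 0 in both directions (65 to 368 at an unadjusted p under 0.05), and 83 to 87 of the 87 genes kept their direction.

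Of 10 lists called by camera, 0 were called with an estimated correlation and 0 by fry. With 1 residual degree of freedom these tests could hardly call any list. camera called 9 with recovered totals or a pseudocount of 0.1, and 10 with voom, a pseudocount of 5 or at least 50 reads. Leave-one-out fits called 5 to 11, and only the proliferation and mitochondrial lists were called in all 4. Directions turned for endoplasmic reticulum stress (0.25 without the exosome library of pair 1; range 1.24e-05 to 0.282), heat shock (0.717 without the control library of pair 2; 0.000533 to 0.931), the memory list (0.766 and 0.956 without the control library of pair 1 and the exosome library of pair 2; 3.19e-07 to 0.956), ribosomal proteins (0.718 without the exosome library of pair 2; 2.62e-13 to 0.9) and the type I interferon response (0.691 without the exosome library of pair 1; 2.02e-05 to 0.691). These are camera adjusted p-values, and the cause was not tested.

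The correlation of folds between pairs was 0.346 with a prior count of 10, 0.348 on log2(value + 1) and 0.41 with at least 50 reads, against 0.312. Genes changed 2-fold the same way numbered 83, 72 and 82 under these, against 162. With at least 50 reads, 717 genes changed 2-fold in pair 1 and 235 in pair 2, and in pair 2 the count was 319 with a prior count of 10 and 291 on log2(value + 1). The authors' shared calls fell from 228 to 55 at an absolute log2 fold of 1 and to 3 at 2, by construction of the stricter limit; a limit of 50 reads removed none.

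Of the 35 called genes that are named, 34 stayed called by DESeq2 (all but VEGFA, adjusted p = 0.342 by DESeq2) and 35 with a pseudocount of 5, and 0 by edgeR, voom, limma without the block or with a pseudocount of 0.1. None of these 35 turned its direction in these fits. None did so in either pair alone, which the paired call in effect requires. Of the other named genes, SIK1, PRDX6, NETO2 and CD4 had the opposite sign in pair 2 alone and CD8B in pair 1 alone; none of these was called.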

Other observations

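The tests of the authors' scaling, of a uniform mitochondrial loss, of the respiratory chain of both genomes, of dilution, of a bias with expression level, of exosome exposure and of carried-over lymphoma RNA were chosen after the result was seen; the test of the response to IL-2 was written before.

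CISH, a negative regulator of cytokine signalling and a target of STAT5, was lower by limma (log2 fold -1.20), beside LIF and OSM; it was chosen after its values were seen. A lower response to the IL-2 in the medium was examined with 11 other STAT5 targets, whose median log2 fold was -0.562 in pair 1 and -0.191 in pair 2. The percentile among matched random lists was 0.05 in pair 1 and 5.67 in pair 2, against a bound of 5 fixed before the data were examined for these genes. A lower response to IL-2 could underlie part of the pattern, and the test leaves it open.

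The 9 measured members of the mitochondrially encoded list were lower in both pairs. Their median lay 0.816 (value -0.816) and 1.33 (value -1.33) below that of the other genes in pair 1 and pair 2, a gap that the authors' per-library scaling cannot make by construction, since 1 factor moves all genes alike; this restates the pattern and is not a further test. COX1, the most abundant of the 9 members, had a limma log2 fold that lay 0.924 ± 0.252 (SE) above the median of the others. The adjusted p was 0.0277 by Bonferroni over the 9, with limma's pooled variances, and COX1 lay on the same side in both pairs. A uniform loss of mitochondrial RNA as the whole cause would leave no such gap. Among the 9 members such a gap was found for COX1 alone. The COX1 test is the last of 3 tests tried on this question with the folds already known. Its adjustment does not cover those 3 tests, so it cannot decide, and a uniform loss stays open. The ratio of the log2 fold of COX1 to that of CYTB (0.0739 in pair 1 and 0.0871 in pair 2) compared members picked as extremes. The order of all 9 folds correlated between pairs at 0.583 (Spearman, exact p = 0.108). Reads from nuclear copies of mitochondrial genes were not tested. The list was matched by symbol, so mitochondrial transcripts without a symbol are not covered. ENSCAFG00000022709, unnamed and numbered near ND1, rose from 252 to 646 and from 375 to 1140 (limma adjusted p = 0.0164). ENSCAFG00000022744, numbered near CYTB, fell from 121 to 46.0 and from 137 to 39.6 (0.0139). Both were chosen after their values were seen, and whether either is mitochondrial was not tested. A lower respiratory chain of both genomes may be involved but stays open, since the nuclear list lay at percentile 52.6 in pair 1 and 2.9 in pair 2.

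Of 4 mitochondrial genes held in pair 1's table alone, ND2 stood at 2218.5 in the control and 945.7 with exosomes, ND4 at 6743.3 and 4317.7, ATP6 at 6485.5 and 4474.2, and COX3 at 4489.4 and 3443.9. These 4 genes lay outside the naming rule.

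Proliferation and cholesterol synthesis genes were lower in both pairs. Dilution by cells that are not T cells would lower CD8 T cell markers as well, and is argued against in pair 2. There the ratio of their median log2 fold to that of the proliferation list was -0.0111, and to that of the cholesterol list -0.0206. In pair 1 the ratios were 0.414 and 0.755, which leaves dilution open as part of the difference there. A bias with expression level is argued against by matched random lists, of which at most 0.01% reached the list medians. Exosome exposure and other differences between the culture arms cannot be told apart: the percentile computed for exosome exposure (at most 0.01) restates the pattern and decides nothing.

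RNA of the lymphoma line carried over with the exosomes would be likely to raise B cell transcripts, yet the median log2 fold of 8 markers was -0.872 in pair 1 and -0.216 in pair 2. Of the 8, 0 had 50 reads in the higher library of both pairs, so the carry-over of lymphoma RNA stays open at this depth. The rule that reads this test by its depth was changed after its first value was seen.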
